A study of Dugesia japonica with 18 samples.

How the data were processed

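The series holds mRNA sequencing of the planarian Dugesia japonica in 18 libraries: head, trunk and tail, each at days 0, 1, 3, 5, 7 and 10, with 1 library per fragment and day. Per the labels' protocols each library was made from a pool of 10 to 20 animals and from RNA enriched for polyA. The meaning of day 0 is not given in the sources used here. Per the submitters' processing notes, reads were checked with FastQC, trimmed with fastp 0.20.0, mapped with Bowtie2 to assembled transcripts and quantified with RSEM. The authors deposited raw counts per unigene in a single file, as the file header calls them, with protein database descriptions. These counts are whole numbers, whereas RSEM estimates need not be, so rounding before deposit is possible. It has 267235 unigenes, of which 22624 have no count in any library; 3 lines with unreadable content were emptied. Other values in the file were not used here.

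CPM and log2 values were computed here from the deposited counts. Library totals ran from 17547716 to 21229980 counts, so that 3 counts, the floor used for detection, were 0.107 to 0.252 CPM. Unigenes with at least 1 CPM in at least 3 libraries were tested, 23616 in all, which held 98.3 to 99.3% of the counts; 8353 of them have a usable name, with 5792 different names. Names come from the protein descriptions in the file. Near-identical copies and paralogs may share reads, so counts of single members of a family are uncertain. TMM factors ran from 0.679 to 1.51.

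Day and fragment contrasts used the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) on fragment plus day, with robust fitting, 10 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. In this additive model the other fragments stand in for replicates of a day and the other days for replicates of a fragment. So p-values rest on fragment-by-day deviations mixed with library noise, not on the spread between replicate pools or animals. Changes over days that differ between fragments enter this error. An F test asked whether a unigene changed on any day. A second F test, with 8 residual degrees of freedom, asked whether slopes over log2(day + 1) differed between fragments. Errors after ± are SE for log2 values and slopes and SD for CPM. Confidence intervals and floors cover counting error only. The size of a fold change is not well determined for unigenes with libraries that hold no count. At day 0, fragments were compared by the log2 ratio of TMM-scaled CPM with a floor of 1 and no test, and list medians were ranked among 10000 random lists drawn from 20 expression bins.

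Gene lists were fixed before the data were examined, and 25 with at least 3 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The preset called 64 of 200 list tests and the estimate 0 (0.117 was its lowest adjusted p), so list calls rest on the preset. Members were matched by protein name. Symbols shorter than 5 characters were not matched, a departure from the plan, and 20 name patterns were left out of lists on their protein names before any test.

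The rule for named genes was fixed in advance. It took up to 4 members of each list past the threshold with the largest log2 fold and the same sign in all 3 fragments or at least 5 of 6 days, the 5 highest and 5 lowest annotated unigenes, and a fixed set of m6A, Wnt, Piwi, PCNA and opsin genes. As this gave more genes than a text can hold, it was shortened after the list results were seen to 2 members per called list, or 4 in the trend. Members of 6 lists (wound-induced, collagen and matrix, dorsoventral BMP, apoptosis, protonephridia and innate immunity) were added after their values were seen, Early growth response protein 4 among them. A unigene that the rule names is not reported here, for a reason unrelated to its values.

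Tests were run on simulated data with 100 changed unigenes per fold, all above a set mean count. Of the 2-fold changes, edgeR found 64 at day 5, 95 between head and tail and 10 in the trend. Of the 4-fold changes it found 97, 100 and 75. False calls numbered 10, 10 and 5. These rates hold for the simulation, with few changes, and not for tested unigenes of lower count. Alternatives were DESeq2 1.42.0 as scaling and as test, other filters, models without a block, parts of the libraries and fry. Library totals in place of TMM, leaving out the top unigene or the head day 1 library, an older edgeR fit, lists without name exclusions and plain CPM at day 0 were added after the data had been seen. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and the R package data.table (1.17.8), and figures drawn with matplotlib 3.10.9.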

Results

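The series measured mRNA in the planarian Dugesia japonica, a flatworm that can rebuild a whole body from a fragment. Animals were cut into head, trunk and tail, and the labels name days 0, 1, 3, 5, 7 and 10 for each fragment. This gave 18 libraries, 1 per fragment and day, each a pool of 10 to 20 animals, so no fragment and day had a repeat. The labels do not say what day 0 is or how long after the cut each pool was taken. The series title names the methylated base m6A and the head-to-tail axis as its subject. Library totals ran from 17547716 to 21229980 counts, and 3 counts, the least taken as detected, equalled 0.107 to 0.252 CPM (counts scaled to a common library total). Of 267235 assembled transcripts (unigenes), 23616 were tested, and 8353 of these carried a protein name. A positive log2 fold change means higher in the first group named, SD is over the 6 days of a fragment, and SE is from the fitted model. Fragment effects averaged over days, and day effects shared by the fragments, come from the same model.

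Fragment was the main difference between libraries. The first principal component held 32.1% of the variance, the second 20.6% and the third 8.43%. Across unigenes, log2 CPM correlated at 0.941 to 0.968 between days of head, 0.960 to 0.974 within trunk and 0.924 to 0.963 within tail. Head and tail of the same day correlated at 0.908 on day 0 and 0.940 on day 10. These are correlations across genes, which are not independent repeats. A single unigene without annotation took 46.3 ± 4.05% of the counts in tail (SD, n = 6 days), 26.7 ± 7.18% in head and 24.1 ± 1.74% in trunk. The scaling of the libraries matters for small differences between fragments. With plain library totals in place of TMM factors, the median log2 fold change of all tested unigenes moved by 0.70 for head against tail, 0.31 for head against trunk and 0.40 for trunk against tail. With totals that leave out that unigene it moved by 0.26, 0.37 and -0.11. Such a shift moves all unigenes nearly alike, so values given below with library totals include it. Relative to the median of all unigenes, 0 of the 64 called list tests and 0 of 188 gene results between fragments changed sign under these scalings, against 9 and 24 that did so against 0 with library totals. The relative counts of 0 were nearly fixed in advance, since a shift common to all unigenes is taken off. They are no test of these results.

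Against tail, the eye and anterior-patterning lists were called higher in head and the muscle list lower. None of these calls held with an estimated correlation (adjusted p = 0.267, 0.320 and 0.267). Rhodopsin (TRINITY_DN127811_c0_g1), the light-absorbing protein of photoreceptors, averaged 92.9 ± 32.2 CPM in head and 2.50 ± 3.98 in tail, a log2 fold change of 5.93 ± 0.93 (SE; adjusted p = 0.000527, higher in head on 6 of 6 days). Beta-arrestin-2 (TRINITY_DN15526_c0_g1, 1 other unigene of the name), which shuts off activated opsins and related receptors, averaged 50.2 ± 17.6 CPM in head and 1.25 ± 1.69 in tail. The receptors NOU-DARAKE (TRINITY_DN5112_c1_g1, log2 2.30 ± 0.47, adjusted p = 0.00256) and nou-darake like-2 (TRINITY_DN3128_c0_g1, 2.33 ± 0.62, adjusted p = 0.0126), of a family that keeps brain tissue inside the head, were higher in head on 6 of 6 days. In the other direction, Wnt-11 ligands, which act in the posterior of planarians, were lower in head by log2 -3.38 ± 0.83 (TRINITY_DN4986_c0_g1, adjusted p = 0.00784) and -4.27 ± 0.65 (TRINITY_DN26781_c0_g1, adjusted p = 0.000258), each on 6 of 6 days.

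In all, 9251 unigenes differed between head and tail, 4614 higher in head and 4637 lower. Library totals gave 17273, with 16153 higher. Totals without the most abundant unigene gave 11042, with 8475 higher. Days 5 to 10 alone gave 5944. Of 195 neuronal unigenes, 130 were higher in head and 14 lower (133 and 16 adjusted over the list alone), with a median log2 fold change of 0.74; the camera set test gave adjusted p = 2.58e-15 at its preset correlation and adjusted p = 0.267 with an estimated correlation. Neuropeptide Y prohormones, precursors of signalling peptides of neurons, led that list: log2 4.29 ± 0.45 for prohormone 1 (TRINITY_DN53767_c0_g2), 3.77 ± 0.38 for prohormone-10 (TRINITY_DN15955_c0_g1) and 3.53 ± 0.35 for prohormone-6 (TRINITY_DN183113_c0_g1). Ionotropic receptor 25a (TRINITY_DN82_c0_g1), a co-receptor of chemosensory neurons in insects, averaged 85.1 ± 8.26 CPM in head and 15.4 ± 20.7 in tail, with log2 3.64 ± 0.76. Peptidase inhibitor 16 (TRINITY_DN4245_c0_g1), a secreted protein of the CAP family, stood at log2 5.05 ± 1.01. Of 17 anterior-patterning unigenes, 14 were higher in head and 0 lower by edgeR (15 and 0 adjusted over the list alone; median log2 1.27; adjusted p = 2.98e-05, and adjusted p = 0.320 with an estimated correlation). The Wnt inhibitors secreted frizzled-related protein B (TRINITY_DN4865_c1_g2, 1.27 ± 0.18, adjusted p = 4.27e-05) and secreted frizzled-related protein 2 (TRINITY_DN146043_c0_g1, 1.85 ± 0.40, adjusted p = 0.00234) were higher in head on 6 of 6 days. So were the ligands Wnt-2b-A (TRINITY_DN14604_c0_g1, 1.31 ± 0.30, adjusted p = 0.00379) and Wnt-5b (TRINITY_DN8726_c0_g1, 0.74 ± 0.17, adjusted p = 0.00233). Eye unigenes were higher in 9 of 16 and lower in 1 (median 1.02; 11 and 1 adjusted over the list alone; adjusted p = 0.0046, and adjusted p = 0.267 with an estimated correlation). Of 18 dorsoventral BMP unigenes, 12 were higher and 0 lower by edgeR (13 and 1 adjusted over the list alone; median 0.44; adjusted p = 0.00185, and adjusted p = 0.291 with an estimated correlation), among them the signal transducer SMAD4 (TRINITY_DN31163_c0_g3, 1.44 ± 0.21) and the inhibitory SMAD6/7-2 (TRINITY_DN28708_c0_g1, 1.42 ± 0.24).

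The intestine, lysosome and mobile-element lists were also called higher in head than in tail (adjusted p = 0.310, 0.540 and 0.267 with an estimated correlation). The intestine list had 18 of 38 higher and 3 lower, with the same counts adjusted over the list alone (median 0.56; adjusted p = 0.000105, and adjusted p = 0.310 with an estimated correlation). Its members included Aminopeptidase N (TRINITY_DN14352_c0_g2, 1.77 ± 0.15), which trims peptides at the gut surface, and Procathepsin L (TRINITY_DN13046_c0_g1, 1.15 ± 0.09), a protease of lysosomes and gut. For lysosome and autophagy, 14 of 31 were higher and 3 lower (14 and 4 adjusted over the list alone; median 0.23; adjusted p = 0.0353, and adjusted p = 0.540 with an estimated correlation). Hexosaminidase beta (TRINITY_DN7761_c0_g1, 0.84 ± 0.12) and lysosomal alpha-mannosidase (TRINITY_DN6789_c0_g1, 0.77 ± 0.24), both of which strip sugars from proteins and lipids, were in it. Mobile elements were higher in 96 of 313 and lower in 24 (95 and 24 adjusted over the list alone; median 0.37; adjusted p = 0.000138, and adjusted p = 0.267 with an estimated correlation), with the DNA transposons Mos1 (TRINITY_DN1881_c0_g3, 1.84 ± 0.31) and Tigger 4 (TRINITY_DN4528_c1_g1, 1.53 ± 0.20). The pharynx and gland list had 6 of 14 higher and 0 lower by edgeR, also adjusted over the list alone (median 0.40; adjusted p = 0.0109, and adjusted p = 0.529 with an estimated correlation), led by the lectin CLEC3A (TRINITY_DN2732_c0_g1, 2.15 ± 0.27) and Astacin-like metalloprotease toxin 1 (TRINITY_DN8051_c0_g1, 1.11 ± 0.18).

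Muscle unigenes were lower in head: 25 of 40 were lower and 4 higher (26 and 4 adjusted over the list alone; median -0.77; adjusted p = 1.62e-07, and adjusted p = 0.267 with an estimated correlation). Troponin I (TRINITY_DN13647_c0_g1), a calcium switch of contraction, averaged 628 ± 141 CPM in head and 1461 ± 298 in tail, and Alpha-actinin (TRINITY_DN30126_c1_g1), which anchors actin filaments, gave log2 -1.15 ± 0.14. Among posterior homeobox genes, php-3 (TRINITY_DN7825_c0_g2) was lower by log2 -2.77 ± 0.38 (adjusted p = 0.000148) on 6 of 6 days. Wnt-4 (TRINITY_DN4149_c0_g1), a posterior Wnt ligand, was lower by -2.12 ± 0.43 (adjusted p = 0.00229). A regulatory subunit of the cAMP-dependent kinase (TRINITY_DN2939_c1_g1, -2.80 ± 0.27) and a scavenger receptor cysteine-rich protein (TRINITY_DN111_c0_g1, -2.21 ± 0.14) were among the 5 lowest. Posterior patterning and Wnt genes as a list were lower in 14 of 30 and higher in 5 (adjusted p = 0.076). Motile cilia (42 of 84 lower, 2 higher; 45 and 2 adjusted over the list alone; median -0.31 over the days, 0.07 at day 0; adjusted p = 4.39e-06, and 0.529 with an estimated correlation) flipped to 0.39 with library totals (-0.34 relative to all unigenes). Wound-induced genes (44 of 128 lower, 14 higher; 47 and 16 adjusted over the list alone; median -0.18; adjusted p = 0.00629, and adjusted p = 0.291 with an estimated correlation) flipped to 0.53 there (-0.20 relative to all unigenes). Cytosolic ribosome proteins (11 of 28 lower, 1 higher, the same adjusted over the list alone; median -0.14; adjusted p = 0.0221, and adjusted p = 0.529 with an estimated correlation) flipped to 0.56 (-0.16 relative to all unigenes). Named members were the cilia motor Dynein axonemal heavy chain 5 (TRINITY_DN20154_c0_g1, -2.24 ± 0.24), the wound-list signalling adaptors TRAF2 (TRINITY_DN6915_c0_g1, -1.68 ± 0.14) and TRAF3 (TRINITY_DN3438_c0_g1, -1.35 ± 0.15), and 40S ribosomal protein S3 (TRINITY_DN969_c0_g1, -0.39 ± 0.12), which flipped to 0.31 with library totals (-0.41 relative to all unigenes). CFAP58 (TRINITY_DN8985_c0_g1), a sperm and cilia protein, went from -0.72 ± 0.12 to -0.02 there. Leaving out a single day ended the calls of S3, of 60S ribosomal protein L6 (TRINITY_DN352_c0_g3, 0.47 ± 0.18), of alpha-mannosidase and of nou-darake like-2, with adjusted p of 0.0533 to 0.121.

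Among the largest differences between head and trunk were secreted proteases and lectins, higher in trunk. Ast6 (TRINITY_DN131044_c0_g1) and Ast4 (TRINITY_DN8325_c0_g2, 1 other unigene of the name), astacin-type metalloproteases, averaged 707 ± 155 and 317 ± 84.9 CPM in trunk against 2.94 ± 4.01 and 2.02 ± 3.07 in head. Hatching enzyme (TRINITY_DN7278_c0_g1), another astacin-type protease, averaged 69.2 ± 15.7 against 0.859 ± 1.28 CPM. The lectin Macrophage mannose receptor 1 (TRINITY_DN21581_c0_g1) averaged 135 ± 29.6 CPM in trunk against 0.484 ± 0.786 in head. The neuronal, eye and anterior-patterning lists were called higher in head than in trunk, as they were against tail (adjusted p = 0.328 for each with an estimated correlation).

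Between head and trunk, 9980 unigenes differed, 4620 higher in head and 5360 lower. Library totals gave 9090 higher and 2585 lower, totals without the most abundant unigene 11036 and 2497. Days 0 to 3 alone gave 6434 in all. The log2 fold changes were -8.96 ± 1.03 for Ast6 (adjusted p = 4.69e-05), -8.63 ± 0.86 for Macrophage mannose receptor 1 (adjusted p = 1.83e-05), -8.23 ± 0.97 for Ast4, -7.63 ± 1.06 for C-type mannose receptor 2 (TRINITY_DN2607_c0_g1) and -6.82 ± 0.85 for Hatching enzyme, each lower in head on 6 of 6 days. The other end held Beta-arrestin-2 (6.06 ± 0.86), Rhodopsin (6.01 ± 0.91), Ionotropic receptor 25a (4.91 ± 0.78), Peptidase inhibitor 16 (4.65 ± 0.97) and neuropeptide Y prohormone-6 (3.72 ± 0.35). Of the neuronal list, 149 of 195 were higher in head and 16 lower (150 and 16 adjusted over the list alone; median 1.06; adjusted p = 2.72e-23, and adjusted p = 0.328 with an estimated correlation). Its extremes were neuropeptide Y prohormone-10 at 3.87 ± 0.36 and neuropeptide precursor-1 (TRINITY_DN17224_c0_g1) at -4.42 ± 0.48, the latter a trunk transcript of 5.54 ± 1.11 CPM. Anterior patterning was higher in 16 of 17 and lower in 0 by edgeR, also adjusted over the list alone (median 1.48; adjusted p = 1.21e-06, and adjusted p = 0.328 with an estimated correlation). NOU-DARAKE stood at 2.47 ± 0.46 and Frizzled-5 (TRINITY_DN5306_c0_g1), a Wnt receptor of the anterior, at 2.07 ± 0.34 (adjusted p = 0.000445). Eye unigenes were higher in 10 of 16 and lower in 0 (11 and 0 adjusted over the list alone; median 0.94; adjusted p = 0.00184, and adjusted p = 0.328 with an estimated correlation). Dorsoventral BMP (median 0.31, 9 higher and 2 lower, also over the list alone; adjusted p = 0.0233, and adjusted p = 0.409 with an estimated correlation) held SMAD6/7-2 at 2.30 ± 0.25 and the BMP antagonist noggin-like 5 (TRINITY_DN2339_c0_g2) at -2.76 ± 0.27. Mobile elements (median 0.14, 69 higher and 30 lower; 66 and 29 adjusted over the list alone; adjusted p = 0.0359, and adjusted p = 0.435 with an estimated correlation) held a Transposase (TRINITY_DN2943_c0_g3) at 1.91 ± 0.36 and PiggyBac (TRINITY_DN4544_c0_g1) at -2.38 ± 0.34.

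The muscle, intestine and ER folding lists were called lower in head than in trunk (adjusted p = 0.328, 0.409 and 0.435 with an estimated correlation). Muscle had 25 of 40 lower and 2 higher (26 and 3 adjusted over the list alone; median -0.69; adjusted p = 3.51e-07, and adjusted p = 0.328 with an estimated correlation), with Myosin light chain kinase A (TRINITY_DN6670_c0_g1, -3.90 ± 0.51) and myosin heavy chain A (TRINITY_DN4102_c0_g4, -1.63 ± 0.39), enzyme and motor of contraction. Intestine had 21 of 38 lower and 5 higher (22 and 6 adjusted over the list alone; median -0.55; adjusted p = 0.000784, and adjusted p = 0.409 with an estimated correlation). The iron store ferritin (TRINITY_DN66338_c0_g1) was lower by log2 -3.23 ± 0.34, and the protease cathepsin L2 (TRINITY_DN60241_c0_g1, 5 other unigenes of the name) averaged 342 ± 295 CPM in head and 1715 ± 642 in trunk. ER protein folding (14 of 23 lower, 2 higher; 14 and 4 adjusted over the list alone; median -0.54; adjusted p = 0.0157, and adjusted p = 0.435 with an estimated correlation) held Protein disulfide-isomerase (TRINITY_DN4236_c0_g1, -1.80 ± 0.29), which forms disulfide bonds, and the ER lectin Calreticulin (TRINITY_DN24633_c0_g3, -1.23 ± 0.29). Cytosolic ribosome (19 of 28 lower, 4 higher, the same adjusted over the list alone; median -0.36, and 0.00 with library totals without the most abundant unigene; adjusted p = 0.000484, and adjusted p = 0.409 with an estimated correlation) held 40S ribosomal protein S7 (TRINITY_DN2799_c0_g1, -0.59 ± 0.07). Medians turned positive with library totals for heat shock (-0.22 to 0.09; 27 of 55 lower), lysosome (-0.24 to 0.07; 17 of 31 lower), collagen and matrix (-0.28 to 0.03; 22 of 41 lower) and DNA replication (-0.30 to 0.01; 17 of 56 lower). Relative to all unigenes, which moved by 0.31, they stood at -0.22, -0.24, -0.28 and -0.30 there. Counting both directions, 31, 21, 30 and 19 of their members were called. Over the lists alone, 28, 18, 22 and 16 were lower. These lists had adjusted p of 0.00327, 0.0233, 0.0233 and 0.0467, and adjusted p = 0.328, 0.572, 0.409 and 0.695 with an estimated correlation. Large differences in them were Collagen alpha-1(XII) (TRINITY_DN6768_c0_g1), a matrix protein, at -5.04 ± 0.60, Matrix metalloproteinase-20 (TRINITY_DN67421_c0_g2) at -3.31 ± 0.26, the autophagy enzyme ATG7 (TRINITY_DN15399_c0_g3) at -0.97 ± 0.12, lysosomal alpha-glucosidase (TRINITY_DN8097_c0_g1) at -1.12 ± 0.26, DNA polymerase epsilon subunit A (TRINITY_DN5813_c0_g1) at -1.01 ± 0.24 and the topoisomerase TOP2B (TRINITY_DN2211_c0_g1) at -1.11 ± 0.36. The chaperone HSP90-beta (TRINITY_DN5658_c0_g3) was at -1.41 ± 0.38. Among the genes always named, proliferating cell nuclear antigen (PCNA, TRINITY_DN23406_c0_g1), the clamp of DNA replication, was lower in head by -0.90 ± 0.20 (adjusted p = 0.0021), while Wnt-11b-2 (TRINITY_DN10261_c1_g1, 1.91 ± 0.31, adjusted p = 0.00011) and the Wnt inhibitor NOTUM (TRINITY_DN14791_c0_g1, 1.25 ± 0.35, adjusted p = 0.00934) were higher, on 6 and 5 of 6 days. Leaving out a single day ended the calls of TOP2B (adjusted p up to 0.0788) and of 40S ribosomal protein S25 (TRINITY_DN38178_c3_g1, 1.93 ± 0.60, adjusted p = 0.107 without day 3), whose profile over libraries follows that of ciliate-like unigenes.

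The intestine list and the pharynx and gland list were called higher in trunk than in tail (adjusted p = 0.117 and 0.594 with an estimated correlation). Zinc transporter ZIP12 (TRINITY_DN17007_c0_g1), which imports zinc into cells, averaged 17.3 ± 3.41 CPM in trunk, 0.226 ± 0.0427 in tail and 0.291 ± 0.133 in head (log2 6.22 ± 0.21 for trunk against tail, adjusted p = 2.68e-13, higher on 6 of 6 days). The proteases Ast6 (8.29 ± 1.01, adjusted p = 0.000127), Ast4 (7.63 ± 0.96) and Hatching enzyme (6.47 ± 0.88) and the lectin Macrophage mannose receptor 1 (6.998 ± 0.80) were again far higher in trunk. Hatching enzyme and Macrophage mannose receptor 1 had no count in a tail library, so the size of their folds is not well determined. Silk gland factor 1 (TRINITY_DN5469_c2_g1), a FoxA-type transcription factor that marks pharynx in planarians, averaged 14.7 ± 2.20 CPM in trunk and 5.33 ± 3.77 in tail (1.87 ± 0.60, adjusted p = 0.031, higher on 6 of 6 days).

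The count was 8661 unigenes, 4323 higher in trunk than in tail and 4338 lower. Library totals gave 9692 higher and 1125 lower, totals without the most abundant unigene 3137 and 5666. Days 0 to 3 alone gave 5122 in all. Intestine had the lowest adjusted p of any list with an estimated correlation: 32 of 38 were higher and 2 lower, the same adjusted over the list alone (median 1.04; adjusted p = 1.29e-14 at the preset, adjusted p = 0.117 with an estimated correlation). Ferritin was higher by 3.62 ± 0.40 (adjusted p = 8.39e-06) and cathepsin L2 by 3.07 ± 0.45 (adjusted p = 0.000397), each on 6 of 6 days. Pharynx and gland had 7 of 14 higher and 0 lower by edgeR, and 8 and 1 by DESeq2 and at unadjusted p under 0.05 (8 and 1 adjusted over the list alone; median 0.79; adjusted p = 0.000792, and adjusted p = 0.594 with an estimated correlation). Lysosome had 16 of 31 higher and 2 lower (17 and 2 adjusted over the list alone; median 0.30; adjusted p = 8.03e-05, and adjusted p = 0.594 with an estimated correlation), with alpha-glucosidase at 1.87 ± 0.27 and hexosaminidase beta at 1.66 ± 0.13. Proteasome was higher in 15 of 27 (16 adjusted over the list alone; median 0.27; adjusted p = 0.000792), ER folding in 11 of 23 (also over the list alone; median 0.31; adjusted p = 0.00163) and heat shock in 20 of 55, lower in 5 (also over the list alone; median 0.16; adjusted p = 0.0206). These 3 lists each had adjusted p = 0.594 with an estimated correlation. Members were Protein disulfide-isomerase at 1.52 ± 0.30, Protein disulfide-isomerase 2 (TRINITY_DN20373_c0_g1) at 0.92 ± 0.07, proteasome activator subunit 3 (TRINITY_DN34606_c0_g1) at 0.61 ± 0.12 and 26S proteasome non-ATPase subunit 2 (TRINITY_DN30337_c0_g1), part of the lid and base that feed proteins to the protease, at 0.47 ± 0.08. The neoblast list, RNA regulators of planarian stem cells, was higher in 10 of 24 and lower in 1 (12 and 3 adjusted over the list alone; median 0.35; adjusted p = 0.0203, and adjusted p = 0.634 with an estimated correlation), with a Piwi-like protein (TRINITY_DN13637_c0_g1), which guides small RNAs in stem cells, at 1.10 ± 0.33. Cytosolic ribosome was higher in 14 of 28 and lower in 4 (14 and 5 adjusted over the list alone; median 0.22; adjusted p = 0.036, and adjusted p = 0.699 with an estimated correlation), although 40S S3 stood at -0.57 ± 0.13.

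On the tail side, the neuronal list had 65 of 195 lower in trunk and 20 higher (68 and 22 adjusted over the list alone; adjusted p = 0.00532, and adjusted p = 0.705 with an estimated correlation), with a median of -0.26 that flipped to 0.13 with library totals (-0.26 relative to all unigenes). Motile cilia had 39 of 84 lower and 1 higher (43 and 1 adjusted over the list alone, with adjusted p = 1.18e-06, and adjusted p = 0.634 with an estimated correlation), with a median of -0.35 that went to 0.03 (-0.36 relative to all unigenes). Both list results are averages over days. At day 0 the trunk minus tail median was -0.0068 for neuronal, with 10 at least 2-fold higher in trunk and 8 lower. For motile cilia it was 0.0084, with 2 higher and 0 lower. The RNA-binding protein CUGBP Elav-like 3-A (TRINITY_DN530_c0_g1), a splicing regulator of neurons, was lower in trunk at -0.85 ± 0.12, whereas neuropeptide precursor-1 (4.24 ± 0.53) and the vesicle protein Synaptotagmin-17 (TRINITY_DN42837_c0_g1, 2.33 ± 0.29) were higher. Of the cilia proteins, CFAP53 (TRINITY_DN19724_c0_g1) was at -0.74 ± 0.13 and CFAP58 at -0.72 ± 0.12, and both lost their call with library totals. Unigenes higher in tail than in trunk included 70 kDa neurofilament protein (TRINITY_DN25739_c0_g3, 697 ± 194 CPM against 196 ± 46.9 in trunk), an intermediate filament. Others were Cyclin-dependent kinase 1-A (TRINITY_DN1119_c0_g1, 40.3 ± 19.2 against 10.9 ± 1.90), a 16 kDa calcium-binding protein (TRINITY_DN12430_c0_g1, 79.9 ± 28.6 against 26.2 ± 5.69) and PLG (TRINITY_DN9101_c0_g1, 48.4 ± 11.6 against 16.97 ± 5.17). ORF91 (TRINITY_DN406_c0_g1, of unknown function) averaged 52.9 ± 119 CPM in tail, a mean set by the 296 CPM of tail day 10. Leaving out a single day ended the calls of Silk gland factor 1 (adjusted p up to 0.0792), the Piwi-like protein (0.0624), S25 (-1.93 ± 0.64, up to 0.207) and Heat shock 70 kDa protein 14 (TRINITY_DN89027_c0_g1, -1.20 ± 0.42, up to 0.148). HSP90 (TRINITY_DN156700_c0_g1), at 6.58 ± 1.05 for trunk against tail and -2.63 ± 0.63 for head against trunk, lost both calls without day 1 (adjusted p = 0.159 and 0.121) and with DESeq2 (adjusted p = 0.727 and 0.635).

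Unigenes called at day 1 included a chaperone, an early-response transcription factor and a Wnt ligand. Heat shock cognate 71 (HSC71, TRINITY_DN204_c0_g1, 2 other unigenes of the name), which refolds and escorts proteins, went from 616 to 2330.2 CPM in head between days 0 and 1, from 788 to 2892 in trunk and from 582 to 3311 in tail. Early growth response protein 4 (TRINITY_DN4276_c0_g1), a zinc finger factor of a family switched on within hours of wounding, went from 0.927 to 15.9 CPM in head, 0.869 to 6.91 in trunk and 1.01 to 14.7 in tail. It was added from the wound-induced list after its value was seen. That list was not called at day 1 (median -0.07; 1 of 128 higher and 0 lower by edgeR, 4 and 10 at unadjusted p under 0.05, 1 and 1 by DESeq2; 2 and 2 adjusted over the list alone; adjusted p = 0.367). Wnt-11b-2, a Wnt ligand by its best protein hit, went from 3.16 to 8.52 CPM in head, from under 3 counts to 2.14 in trunk and 1.09 to 7.41 in tail. At day 5, the muscle and motile cilia lists were called lower than at day 0 at the preset correlation (adjusted p = 3.81e-06 and 2.86e-15) and not with an estimated one (adjusted p = 0.463 for both).

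At day 1, 72 unigenes were higher than at day 0 and 24 lower. The count of 96 was 57 without the head day 1 library, 31 without head, 18 without tail and 10 with no fragment block. It was 222 by DESeq2 or with only the libraries compared. A filter of 10 counts in total gave 243. The log2 fold changes were 3.76 ± 0.31 for Early growth response protein 4 (SE; adjusted p = 7.92e-06), 2.12 ± 0.15 for HSC71 (adjusted p = 2.6e-06) and 2.09 ± 0.40 for Wnt-11b-2 (adjusted p = 0.0259), each higher in 3 of 3 fragments. NOTUM, a Wnt inhibitor made at wounds facing forward, went from 1.43 to 13.7 CPM in tail, 0.613 to 4.62 in trunk and 3.46 to 3.78 in head. Its 2.002 ± 0.50 had adjusted p = 0.119 by edgeR and, over any day, adjusted p = 0.000185 by DESeq2. The proteasome list, the machinery of protein breakdown, was higher in 2 of 27 and lower in 0 (13 and 0 adjusted over the list alone; 23 members positive; median 0.27; adjusted p = 2.20e-08, and adjusted p = 0.259 with an estimated correlation), with proteasome subunit alpha type 6 (TRINITY_DN185633_c0_g1) at 0.74 ± 0.15. Heat shock and chaperones were higher in 5 of 55 (9 adjusted over the list alone; median 0.11; adjusted p = 0.000166, and adjusted p = 0.259 with an estimated correlation). ER protein folding was higher in 2 of 23 (6 adjusted over the list alone; median 0.16; adjusted p = 0.000166, and adjusted p = 0.411 with an estimated correlation), with Calreticulin (TRINITY_DN157_c0_g2) at 1.04 ± 0.13 and the ER chaperone Endoplasmin (TRINITY_DN2681_c0_g1) at 0.93 ± 0.14. HSP90 (TRINITY_DN156700_c0_g1) had 0 counts in the 3 day 0 libraries and reached 29.3 CPM in trunk, 7.45 in head and 0.255 in tail, a rise called by edgeR over any day (adjusted p = 0.00274) and not by DESeq2 (adjusted p = 0.614). DNA replication had a median of 0.27 with 46 of 56 members positive and 0 called by edgeR, also adjusted over the list alone (2 at unadjusted p under 0.05, 0 by DESeq2; adjusted p = 0.000683, and adjusted p = 0.937 with an estimated correlation). The neoblast list had a median of 0.20 with 19 of 24 positive and 0 called by edgeR (3 at unadjusted p under 0.05, 0 by DESeq2; adjusted p = 0.00133, and adjusted p = 0.532 with an estimated correlation). Muscle moved the other way, with a median of -0.35 and 1 unigene called in each direction (12 lower and 2 higher adjusted over the list alone; adjusted p = 8.93e-07, and adjusted p = 0.411 with an estimated correlation). Trunk went against 4 of these lists between days 0 and 1. Its mean log2 CPM was 5.27 and 5.06 for ER protein folding, 3.11 and 3.03 for DNA replication, 4.69 and 4.60 for neoblast, and 6.59 and 6.67 for muscle.

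At day 3, 175 unigenes were higher than at day 0 and 137 lower. The balance turned with a filter of CPM 5 (90 higher, 116 lower), the older edgeR fit (92 and 108) and without trunk (78 and 83). In all 32 were called without head, 6 without tail, 2 with no fragment block, 474 by DESeq2 and 709 with only the libraries compared. A papain family cysteine protease (TRINITY_DN143909_c0_g1), of a class that digests protein, rose by 3.51 ± 0.74 (adjusted p = 0.0447), from 2.23 to 35.6 CPM in head, 2.86 to 33.7 in tail and 0.767 to 3.21 in trunk. It shares its profile over the libraries with ciliate-like unigenes, as do 53 of the 175, including 60S ribosomal protein L5 (TRINITY_DN15551_c0_g1, 4.26 ± 0.70) and 60S ribosomal protein L4 (TRINITY_DN42426_c0_g1, 2.61 ± 0.52). A replication-associated protein (TRINITY_DN237_c0_g1), of the kind circular DNA viruses use to copy themselves, fell from 17.03 to 2.59 CPM in head, 23.4 to 7.75 in trunk and 20.3 to 3.41 in tail (-2.32 ± 0.35, any-day adjusted p = 0.0029). Muscle had 6 of 40 lower and 1 higher (12 and 1 adjusted over the list alone; median -0.25; adjusted p = 4.14e-05, and adjusted p = 0.867 with an estimated correlation). Anterior patterning was called higher as a list (median 0.17; 13 of 17 positive, 0 called by edgeR, 3 at unadjusted p under 0.05, 1 by DESeq2; adjusted p = 0.00446, and adjusted p = 0.867 with an estimated correlation), although its mean log2 CPM in head was 3.86 at day 0 and 3.81 at day 3. So were cytosolic ribosome (median 0.08; 2 higher, 5 adjusted over the list alone; 4 of 28 members share the profile of ciliate-like unigenes; adjusted p = 0.018) and proteasome (median 0.10; 24 of 27 positive, 0 called by edgeR, 3 at unadjusted p under 0.05, 0 by DESeq2; adjusted p = 0.018). These 2 lists had adjusted p = 0.867 with an estimated correlation.

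At day 5, 299 unigenes were higher than at day 0 and 988 lower. That this is the largest count of a day depends on the libraries used: only those compared gave 709 at day 3 and 122 at day 5, and without head 109 differed at day 10 and 91 at day 5 (51 of them higher). The day 5 count was 34 without tail, 4 with no fragment block, 756 with a filter of 10 counts in total and 677 with library totals. Motile cilia proteins were lower in 16 of 84 and higher in 0 (51 and 1 adjusted over the list alone; 8 members positive; median -0.45; adjusted p = 2.86e-15, and adjusted p = 0.463 with an estimated correlation). Tektin-3 (TRINITY_DN26821_c0_g1, 3 other unigenes of the name), a filament of cilia, fell by 1.21 ± 0.19 on the log2 scale (any-day adjusted p = 0.00837), from 37.2 to 14.3 CPM in head, 37.4 to 19.0 in trunk and 25.2 to 10.0 in tail. Outer dynein arm-docking complex subunit 2 (TRINITY_DN9281_c0_g1), which anchors cilia motors, fell by 0.73 ± 0.14. The neuronal acetylcholine receptor alpha-7 (TRINITY_DN5420_c0_g1), a fast ion channel, fell by 0.90 ± 0.12, and Protein henna (TRINITY_DN19298_c0_g3), which oxidises phenylalanine, by 1.81 ± 0.42. Cathepsin L1 (TRINITY_DN59224_c0_g1) rose by 4.16 ± 0.70 (adjusted p = 0.00906), reaching 55.3 CPM in head, 24.7 in trunk and 46.0 in tail. Digestive cysteine proteinase 2 (TRINITY_DN5928_c0_g1) rose by 3.29 ± 0.45 and noggin-like 5 by 2.55 ± 0.39 (any-day adjusted p = 0.00645; 36.5 CPM in trunk at day 5). Cholesterol 24-hydroxylase (TRINITY_DN21110_c0_g1), a sterol oxidase, rose by 2.43 ± 0.56 (any-day adjusted p = 0.0472), and the DD34D transposase (TRINITY_DN10724_c0_g1) by 1.70 ± 0.32. Muscle had 10 of 40 lower (15 adjusted over the list alone; median -0.32; adjusted p = 3.81e-06, and adjusted p = 0.463 with an estimated correlation). Epidermal lineage had 1 of 7 lower (4 adjusted over the list alone; median -0.54; adjusted p = 0.004, and adjusted p = 0.463 with an estimated correlation). Mobile elements had 10 of 313 higher and 2 lower (also over the list alone; median 0.23; adjusted p = 0.000155, and adjusted p = 0.463 with an estimated correlation). Anterior patterning (median 0.59; adjusted p = 0.00383), neoblast (0.22; adjusted p = 0.0174) and DNA replication (0.21; adjusted p = 0.00201) were called higher as lists with 0 members called by edgeR and 0 by DESeq2 (1, 4 and 8 at unadjusted p under 0.05), each with adjusted p = 0.691 with an estimated correlation. The fragments did not agree. Between days 0 and 5 the mean log2 CPM went from 3.86 to 3.56 in head for anterior patterning, and in trunk from 4.69 to 4.57 for neoblast and from 3.11 to 2.84 for DNA replication. Cytosolic ribosome had a median of 0.16 and 1 call each way (adjusted p = 0.00383, and adjusted p = 0.691 with an estimated correlation).

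The muscle list was called lower at days 7 and 10 too (adjusted p = 0.527 and 0.779 with an estimated correlation). At day 7, 84 unigenes were higher than at day 0 and 204 lower. At day 10, 90 were higher and 210 lower. Without the head libraries most calls were higher, with 46 higher and 18 lower at day 7 and 93 and 16 at day 10. The counts were 0 and 3 without tail by edgeR, 10 and 21 with only the libraries compared, 2 and 1 with no fragment block, and 120 and 113 with library totals. DESeq2 gave 652, with 273 higher, and 934, with 468 higher. Muscle had 10 of 40 lower at day 7 (18 lower and 1 higher adjusted over the list alone; median -0.37; adjusted p = 2.90e-07, and adjusted p = 0.527 with an estimated correlation). At day 10 it had 8 lower (18 adjusted over the list alone; median -0.40; adjusted p = 6.97e-08, and adjusted p = 0.779 with an estimated correlation). Alpha-actinin fell by 1.19 ± 0.19 at day 7 and the giant spring protein Titin (TRINITY_DN7853_c3_g2, 4 other unigenes of the name) by 1.08 ± 0.17 at day 10 (any-day adjusted p = 0.00624 and 0.00859, lower in 3 of 3 fragments). Pax-6 (TRINITY_DN8427_c0_g2), a transcription factor of brain and eye, rose by 1.16 ± 0.25 at day 7 (any-day adjusted p = 0.0327). Intestine was called lower as a list at both days (medians -0.26 and -0.22; 2 and 1 called lower, 1 higher; 6 and 8 lower adjusted over the list alone; adjusted p = 0.0137 and 0.00178, and adjusted p = 0.669 and 0.779 with an estimated correlation). Its mean log2 CPM in trunk was not lower, at 5.51 on day 0, 5.73 on day 7 and 5.54 on day 10. The urea-cycle enzyme Arginase (TRINITY_DN19602_c0_g1) fell by 1.82 ± 0.29 at day 10, from 691 to 203 CPM in trunk. Cytochrome P450 1A5 (TRINITY_DN22515_c0_g1), which oxidises foreign compounds, fell by 1.81 ± 0.32 and a C-type lectin (TRINITY_DN2145_c0_g2, 7 other unigenes of the name), a sugar-binding protein, by 1.76 ± 0.27 (any-day adjusted p = 0.0194, 0.00693 and 0.0138). Neuronal unigenes had medians of 0.09 and 0.27, with 2 and 4 called lower and 0 higher by edgeR, against 4 and 5 lower and 5 and 18 higher by DESeq2 (33 and 43 higher, 15 and 8 lower at unadjusted p under 0.05; 14 higher and 5 lower at day 10 adjusted over the list alone; adjusted p = 0.00947 and 2.32e-06, and adjusted p = 0.749 and 0.779 with an estimated correlation). CUGBP Elav-like 3-A rose by 0.78 ± 0.17 at day 10 (any-day adjusted p = 0.0365). Choline acetyltransferase (TRINITY_DN10680_c0_g1), which makes acetylcholine, passed the any-day test (0.98 ± 0.25 at day 10, adjusted p = 0.047) and not the day 10 contrast (adjusted p = 0.0836). Anterior patterning had medians of 0.27 and 0.49 with 0 called by edgeR at both days (2 and 5 at unadjusted p under 0.05, 0 and 3 by DESeq2; adjusted p = 0.00124 and 7.93e-05, and adjusted p = 0.669 and 0.779 with an estimated correlation). Eye had medians of 0.17 and 0.07 with 1 and 0 called by edgeR (4 and 3 at unadjusted p under 0.05, 1 and 3 by DESeq2; adjusted p = 0.00947 and 0.0387, and adjusted p = 0.527 and 0.779 with an estimated correlation). In head the mean log2 CPM did not rise with these 3 lists. At days 0, 7 and 10 it was 3.50, 3.43 and 3.49 for neuronal, 3.86, 3.60 and 3.67 for anterior patterning, and 2.21, 2.15 and 2.03 for eye. Motile cilia were called higher as a list at day 10, mostly through tail, with medians of -0.07 in head, 0.11 in trunk and 0.55 in tail (shared median 0.18, 68 of 84 positive, 0 called by edgeR, 21 at unadjusted p under 0.05, 2 by DESeq2; adjusted p = 3.68e-06, and adjusted p = 0.779 with an estimated correlation).

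Over any of the days, 1377 unigenes changed; without tail the count was 33, without head 210 and without trunk 1144. DESeq2 gave 2813 and a filter of 10 counts in total 2141. All members of the muscle, cilia and neuronal lists called over any day numbered 12 of 40, 25 of 84 and 8 of 195 (15, 49 and 5 adjusted over the list alone). The retroelement Transposon Tf2-7 (TRINITY_DN11718_c0_g4) passed that test with 1.83 ± 0.44 at day 1, a contrast that alone did not (adjusted p = 0.0903). Of the unigenes named here with an any-day call, all but HSC71 and Early growth response protein 4 lost it when some fragment was left out; for those the adjusted p stayed at or below 0.000384 and 0.00337.

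Some unigenes of the m6A machinery differed between fragments. METTL3 (TRINITY_DN30538_c0_g1), the enzyme that writes m6A, averaged 9.78 ± 1.49 CPM in head, 9.65 ± 0.743 in trunk and 11.2 ± 1.75 in tail (SD, n = 6 days). Of 17 unigenes, 0 were called over any day by edgeR (3 at unadjusted p under 0.05, 1 by DESeq2) and 0 in the trend over days (0 at unadjusted p under 0.05, 0 by DESeq2), also adjusted over the list alone. Between head and tail 2 were higher and 4 lower (median -0.07, camera adjusted p = 0.531), between head and trunk 1 and 3 (0.01, adjusted p = 0.571), and between trunk and tail 2 and 1 (0.05, adjusted p = 0.920). Calls numbered 6, 4 and 3 of 17, where 39.2, 42.3 and 36.7% of all tested unigenes were called. So the list was not called more often than unigenes in general. METTL3 had a head minus tail log2 of -0.20 ± 0.11 (adjusted p = 0.165), which turned to 0.51 with library totals. Relative to all unigenes it was -0.22 and -0.21. The YTHDF readers, which bind m6A, were lower in head than in tail for YTHDF2 (TRINITY_DN6087_c0_g1, -0.47 ± 0.11, adjusted p = 0.00352, 5 of 6 days) and YTHDF1 (TRINITY_DN77690_c0_g1, -0.34 ± 0.10, adjusted p = 0.0124, 6 of 6 days), which turned to 0.24 and 0.37 with library totals. Relative to all unigenes these were -0.49 and -0.36, and -0.48 and -0.35 with library totals. The other 3 YTHDF-type unigenes had adjusted p of 0.251 to 0.829 between head and tail. METTL14, WTAP, YTHDC1 and ALKBH5 matched no tested unigene by name and are not analysed here.

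Of the stem-cell, Wnt and opsin genes fixed in advance, mostly called ones are given. The Piwi-type protein Ago3 (TRINITY_DN643_c0_g1) was higher in trunk than in tail (0.40 ± 0.09, adjusted p = 0.0015) and lower in head than in trunk (-0.29 ± 0.09, adjusted p = 0.0124), the latter turning to 0.01 with library totals (-0.29 relative to all unigenes). Piwi-like protein 2 (TRINITY_DN3080_c0_g1, 0.58 ± 0.15, adjusted p = 0.00629) and PCNA (TRINITY_DN17885_c0_g1 and TRINITY_DN23406_c0_g1, 0.67 and 0.70, adjusted p = 0.0152 and 0.0156) were higher in trunk than in tail. Over any day the PCNA unigenes had adjusted p of 0.627 and 0.382. Wnt-4 (TRINITY_DN25612_c0_g1) was lower in head than in trunk (-1.99 ± 0.29, adjusted p = 4.71e-05) and higher in trunk than in tail (1.56 ± 0.30, adjusted p = 0.000825). The Wnt carrier wntless (TRINITY_DN8446_c0_g2) was higher in head than in trunk (0.64, adjusted p = 0.000343), and NOTUM did not differ between head and tail (0.22, adjusted p = 0.645). Opsin-3 (DN2907_c0_g1) stood at 0.003 for head minus tail.

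Over the days, some transcripts high in head at day 0 gained in tail, and some high in tail gained in head. In tail, nou-darake like-2 went from 0.504 to 25.2 CPM between days 0 and 10 while head went from 64.6 to 48.6. Frizzled-5 went from 3.87 to 26.1 in tail and the transcription factor SIX6 (TRINITY_DN19235_c0_g1, of a family active in forebrain and eye) from 0.504 to 2.90. Rhodopsin was at 0 counts in tail at day 0 and at 10.2 CPM at day 10, and in trunk went from under 3 counts to 6.65. The posterior homeobox gene php-3 (TRINITY_DN2826_c0_g2) went from 60.3 to 13.8 CPM in tail and from 0.548 to 5.63 in head, as the plot of 6 regional unigenes by day shows.

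**Figure D1:**
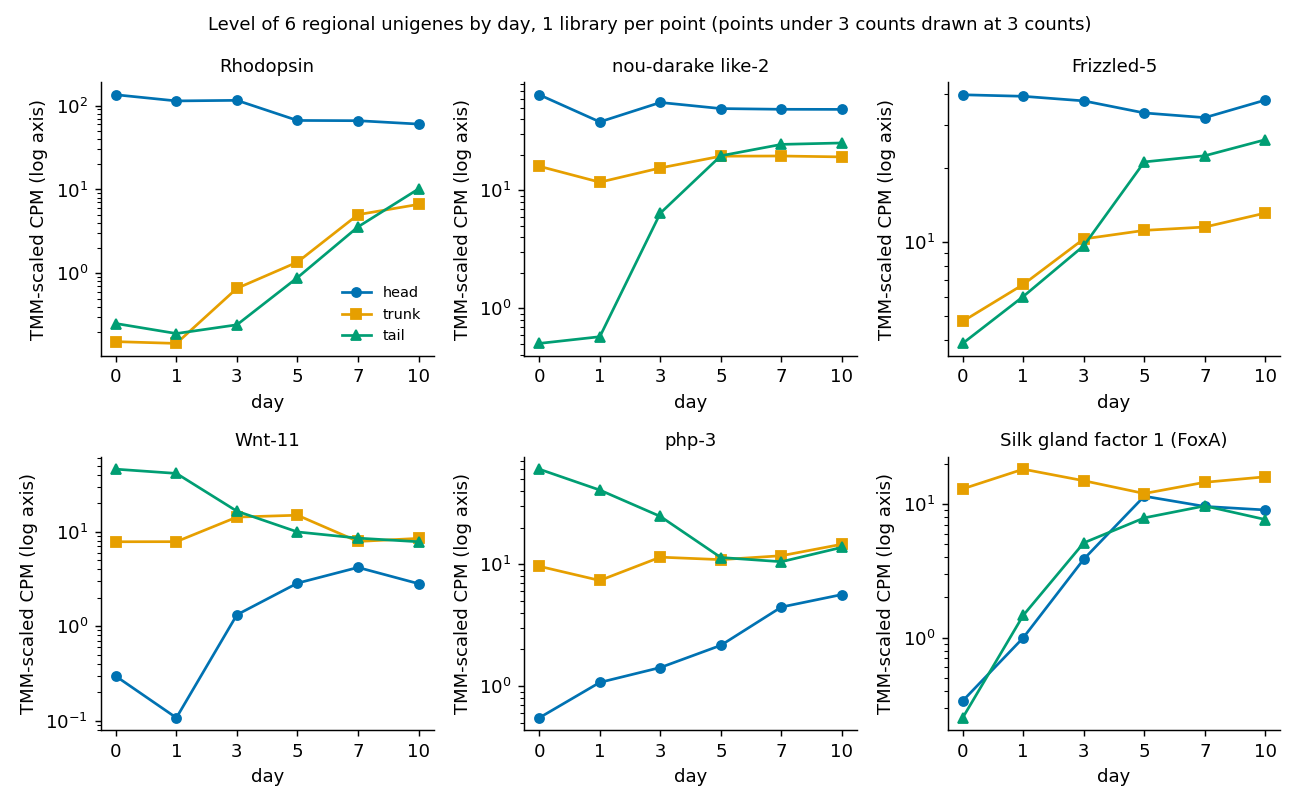
CPM (log axis) by day, equally spaced, for 6 unigenes, 1 point per library and 1 line per fragment; points under 3 counts are drawn at 3 counts. Rhodopsin, nou-darake like-2 and Frizzled-5 climb in tail, to 10.2, 25.2 and 26.1 CPM, Wnt-11 and php-3 decline there, to 7.82 and 13.8, and Silk gland factor 1 climbs in head and tail to 9.002 and 7.63.

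The trend over log2(day + 1) differed between fragments for 718 unigenes. Without day 10 the count was 147, without day 7 264 and without day 1 330, and with a filter of 10 counts in total 1344. Of the 718, 491 had a higher slope in tail than in head and 227 the reverse, and 522 (72.7%, against 55.9% of all tested unigenes) lay closer between head and tail at day 10 than at day 0. Median slopes were 0.40 in tail, 0.08 in trunk and -0.01 in head. Slopes of unigenes with libraries at 0 counts depend on the prior count and bound nothing. Anterior patterning had 9 of 17 called (12 adjusted over the list alone): the head minus tail slope was -1.88 ± 0.16 for nou-darake like-2 (adjusted p = 5.74e-05), -1.28 ± 0.21 for SIX6 (adjusted p = 0.00449), -1.21 ± 0.12 for NOU-DARAKE (adjusted p = 6.17e-05) and -0.93 ± 0.09 for Frizzled-5 (adjusted p = 5.74e-05). Eye had 5 of 16 called, also adjusted over the list alone. Rhodopsin had -3.81 ± 0.26 (adjusted p = 2.42e-07) and Pax-6 (TRINITY_DN8427_c0_g1) -1.46 ± 0.29 (adjusted p = 0.0216; 0 counts to 4.35 CPM in tail). Head minus trunk slopes were -3.68 ± 0.36 for Beta-arrestin-2 and -2.56 ± 0.42 for Tyrosinase (TRINITY_DN10836_c0_g1), which makes eye pigment. Of the neuronal list, 17 of 195 were called (29 adjusted over the list alone). The potassium channel Shaw (TRINITY_DN1199_c0_g1, 11 other unigenes of the name) went from 1.43 to 13.4 CPM in tail, Synaptotagmin-1 (TRINITY_DN532_c0_g1), the calcium sensor of transmitter release, from 42.7 to 159, and the glutamate loader VGLUT 2.1 (TRINITY_DN26388_c0_g1) from 9.50 to 43.3, with head minus tail slopes of -0.85 ± 0.12, -0.59 ± 0.10 and -0.71 ± 0.14. Wnt-2b-A gained in tail (2.02 to 10.4 CPM, -0.75 ± 0.14, adjusted p = 0.012), and secreted frizzled-related protein B had -0.50 ± 0.09 (adjusted p = 0.00984).

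Posterior patterning and Wnt genes had 13 of 30 called (16 adjusted over the list alone). In the members given next, head gained on tail, whereas Wnt-2b-A, given above, moved the other way. Wnt-11 went from 45.9 to 7.82 CPM in tail and 0.295 to 2.82 in head (TRINITY_DN4986_c0_g1, slope difference 2.34 ± 0.36, adjusted p = 0.0125). The second Wnt-11 (TRINITY_DN26781_c0_g1) went from 21.4 to 5.61 in tail and from under 3 counts to 1.11 in head (1.81 ± 0.32, adjusted p = 0.00217) and Wnt-4 (TRINITY_DN4149_c0_g1) from 81.8 to 33.1 and 4.89 to 15.6 (1.06 ± 0.12, adjusted p = 0.000347). The posterior homeobox genes PLOX4 (TRINITY_DN2826_c0_g1, 1.86 ± 0.16, adjusted p = 1.04e-05), php-3 (1.72 ± 0.14, adjusted p = 4.64e-06) and Hox-A7 (TRINITY_DN1859_c0_g2, 1.41 ± 0.21, adjusted p = 0.00142) moved likewise. Pharynx and gland had 6 of 14 called (7 adjusted over the list alone). Silk gland factor 1 went from 0.337 to 9.002 CPM in head and 0.252 to 7.63 in tail while trunk held 12.9 and 15.9 (head minus trunk 1.46 ± 0.23, adjusted p = 0.0053). Macrophage mannose receptor 1 went from 0 counts to 6.81 CPM in tail (trunk minus tail -4.26 ± 0.52, adjusted p = 0.00166, and 0.098 by DESeq2). A C-type lectin (TRINITY_DN35750_c0_g1) fell in head from 36.8 to 8.05 CPM and went from 0 counts to 4.86 in tail, and CLEC3A had a head minus tail slope of -0.63 ± 0.12. The trunk proteases appeared late elsewhere: Hatching enzyme reached 3.17 CPM in head and 4.23 in tail from 0 counts, Endothelin-converting enzyme (TRINITY_DN15312_c0_g1), a peptide-cleaving protease, 2.10 and 2.84 and Carboxypeptidase A2 (TRINITY_DN31582_c0_g1), a digestive enzyme, 1.59 and 2.59. Intestine had 5 of 38 called (15 adjusted over the list alone). Cathepsin L2 went from 853 to 97.8 CPM in head, 823 to 81.6 in tail and 1951 to 1330 in trunk. Gastric lipase (TRINITY_DN11280_c0_g1, 4 other unigenes of the name), a fat-digesting enzyme, went from 88.5 to 18.4 in tail (trunk minus tail 0.60 ± 0.10). Motile cilia had 8 of 84 called (44 adjusted over the list alone), with higher slopes in tail: CFAP157 (TRINITY_DN9098_c0_g1) went from 27.2 to 51.8 CPM there, CFAP91 (TRINITY_DN8935_c0_g1) from 23.5 to 44.9 and Dynein axonemal heavy chain 7 (TRINITY_DN4265_c0_g2) from 81.3 to 129.6. A striated-muscle Myosin heavy chain (TRINITY_DN4102_c0_g2) was called (adjusted p = 0.000133) on 3 libraries alone, head days 7 and 10 (32.0 and 34.9 CPM) and trunk day 1 (43.4 CPM). Leaving out a single day ended the calls of SIX6, Pax-6, Wnt-2b-A, both Wnt-11 unigenes, frizzled-related protein B, Synaptotagmin-1, VGLUT 2.1, Silk gland factor 1, Macrophage mannose receptor 1, CLEC3A, the C-type lectin, gastric lipase and the 3 cilia unigenes.

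At day 0 there was 1 library per fragment and so no test. Anterior patterning had a median head minus tail log2 of 2.26 and head minus trunk of 2.01, with 13 and 11 of 17 at least 2-fold higher in head and 0 lower. Among 10000 random lists of like expression, both medians stood at the 100th percentile. Eye (0.95; 8 of 16) and neuronal unigenes (0.91; 91 of 195 higher, 5 lower) were also at the 100th percentile against tail. Posterior patterning and Wnt had a median of -0.58 with 11 of 30 at least 2-fold lower in head and 4 higher. Pharynx and gland (1.32; 9 of 14) and intestine (0.996; 19 of 38) were higher in trunk than in tail. DNA replication, a mark of dividing cells, had a head minus trunk median of -0.61 with 20 of 56 lower and a trunk minus tail median of 0.52. In all, 3506 unigenes differed at least 2-fold between head and tail, 3103 between head and trunk and 2854 between trunk and tail. Plain CPM gave 6946 (6584 higher in head), 3477 (2243 higher in head) and 5266 (5003 higher in trunk). A floor of CPM 5 gave 1627, 1275 and 1013.

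The head minus tail medians of the regional lists moved toward 0 by day 10. They are taken from log2 CPM with a prior count of 2. So their day 0 values differ from those given above with a floor of 1 CPM. Anterior patterning went from 2.60 at day 0 to 0.56 at day 5 and 0.55 at day 10, eye from 1.09 to 0.66 and neuronal from 1.001 to 0.39. Posterior patterning went from -0.56 to -0.11, and from 0.23 to 0.30 with library totals. Relative to all unigenes these were -0.57 and -0.18, and -0.57 and -0.19 with library totals. The sign thus depends on the scaling. The values relative to all unigenes hardly can, because a change of scaling moves all unigenes nearly alike, so they are no check. Over all tested unigenes, the median absolute log2 difference between head and tail was 0.467 at day 0 and 0.428 at day 10. Between head and trunk it went from 0.421 to 0.454, while 1 minus the Spearman correlation turned the other way (-0.0128). Between trunk and tail it went from 0.469 to 0.443.

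**Figure D2:**
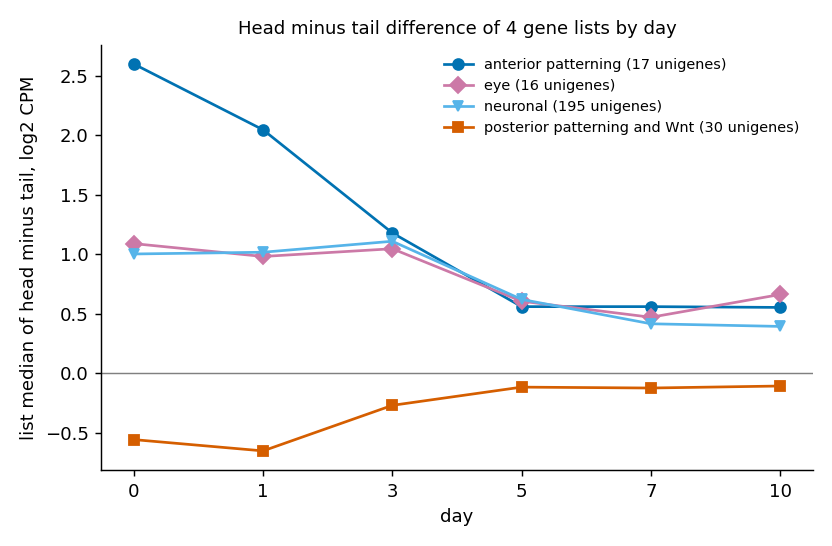
Median head minus tail log2 difference of 4 gene lists by day, equally spaced, 1 library per fragment and day and no error bar. Anterior patterning declines from 2.60 to 0.55, eye from 1.09 to 0.66 and neuronal from 1.001 to 0.39, and posterior patterning and Wnt goes from -0.56 to -0.11 with TMM factors and from 0.23 to 0.30 with library totals, which are not drawn and stand at -0.57 and -0.19 relative to all unigenes.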

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

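All tests of ciliate reads, the second mixing test with its bound of 2 and the single-library test of the cilia were chosen only after the result was seen; the first mixing test and the scaling tests were set before. In head day 1 the most abundant unigene took 12.98% of the counts, against 26.2 to 32.2% in the other head libraries, and in trunk day 5 the next 10 unigenes took 8.03%, against 5.56 to 6.38% in the other trunk libraries. A library far from the others of its fragment drew attention here, by Dixon's test in 2 of 18 groups (6 measures in 3 fragments, both ends tested); days are not replicates, and about 1 in 20 groups would pass by chance.

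A difference between fragments in their change over the days drew attention to 718 unigenes, among them 9 of anterior patterning, 5 of eye, 5 of intestine, 8 of motile cilia, 17 of neurons, 6 of pharynx and gland and 13 of posterior patterning and Wnt. With days shuffled within fragments, 1 of 100 splits, the real one, called as many; the highest other called 541 and the next 82.

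Tails gained unigenes of the head region. Of 155 unigenes at least 8-fold higher in head at day 0, the median tail level was 5.84% of head at day 0 and 35.0% at day 10. Head RNA mixed into the tail day 10 library could raise all of them: only 1.94% stayed below 0.5 times the opsin share of 16.8%, so mixing fits that first test. Any other broad rise could pass that test too, so it cannot decide for mixing. As the whole rise, mixing predicts nearly equal shares of head, but those of unigenes under 1 CPM in tail at day 0 had a quartile ratio of 2.36. Head counts down to 48 and tail levels of up to 1 CPM at day 0 could also spread these shares. So the ratio does not exclude mixing. The opsin unigene stood at 0% of head in tail at day 0, so mixing could add at most about its day 10 share. Of the 155, 120 rose by more percentage points than that share. For those 120 the values argue against mixing as the whole rise, and leave it open as a part. The median tail level was 6.44% of head at day 3, 11.1% at day 5 and 19.1% at day 7. Mixing into the day 10 library alone would not give that earlier rise. The choice between TMM and library totals did not make the rise, as 9 of 9 called anterior patterning unigenes kept call and direction with library totals. What else adds to the rise was not tested.

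Of 175 unigenes higher at day 3, 30.3% follow the common profile of unigenes whose best hit is a ciliate. That share settles nothing, because the unigenes were chosen on day 3 and the profile itself is highest there. Over the 12 libraries of the other days after day 0, 16.1% of the 168 with no ciliate hit follow the profile taken there, against 0.534% of all tested, and 0 of 17 with a planarian best hit do. Reads from ciliates could thus be the source of part of these rises. Of the 175, 43.4% correlate below 0.5 with the profile over all libraries. That does not exclude ciliates as their source, since only 21 of the 45 tested ciliate-hit unigenes follow their own profile. Only the 17 with a planarian best hit speak against ciliates as the source of all the rises. The first test, on the summed level of ciliate-like unigenes, gave 0% and was set aside after it was seen, because 5 unigenes make up 71.8% of the sum. The profile over all libraries is also followed by 130 of 9980 head vs trunk calls, 103 of 8661 trunk vs tail calls and 76 of 1377 any-day calls. Between head and tail it is 0 of 9251. So do 4 of 28 cytosolic ribosome and 4 of 55 heat shock members, against 0.855% of all tested.

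Motile cilia unigenes were lower at day 5 in each fragment, with list medians of -0.64 in head, -0.43 in trunk and -0.26 in tail, which excludes a single library as the cause. The highest median over 3 scalings was -0.39. These shift the day 5 median of all unigenes by only 0.010, 0.033 and 0.064, too little to undo the fall. So the fall does not come from the choice among them, and the test says nothing of larger shifts. Transcript length and RNA quality were not used here, so they may still contribute.

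Random regroupings called 5587 unigenes at most between head and tail (real 9251), 5452 between head and trunk (9980), 4758 between trunk and tail (8661) and 75 over any day (1377). In each, only the real one of 100 splits reached that count. That excludes chance alone, not a cause shared by a group's libraries. For single days 10 splits are too few to say: real counts of 96, 312, 1287, 288 and 300 stood against 5, 3, 0, 3 and 2 in the highest other.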

How the results depend on the processing

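Pairing beyond fragment and day was not possible because the labels carry no replicate numbers. The additive model already compares days within fragments and fragments within days. Day counts depend on settings far more than fragment counts; except where construction is named, the cause was not tested. For days 1, 3, 5, 7 and 10 the main counts were 96, 312, 1287, 288 and 300, and 1377 over any day. The DESeq2 test gave 222, 474, 652 and 934 at days 1, 3, 7 and 10 and 2813 over any day, with 41.9 and 50.1% higher at days 7 and 10 against 29.2 and 30%. A filter of 10 counts in total gave 243 at day 1, 756 at day 5, 2141 over any day and 1344 for the trend (718), with 42.5 and 47.6% higher at days 7 and 10; CPM 5 gave 206 at day 3. Only the libraries compared, 6 per test, gave 222, 709, 122, 10 and 21, and no fragment block 10, 2, 4, 2 and 1. Leaving out a fragment, which removes 6 libraries, gave 18–119, 6–161, 34–1059, 0–353 and 3–519, and 33–1144 over any day, each lowest without tail and highest without trunk; without head they were 31, 32, 91, 64 and 109, and 210 over any day. Without day 10, 7 or 1 the trend gave 147, 264 and 330 (range 147–785). Days 0 to 3 alone gave 6434 for head vs trunk (9980) and 5122 for trunk vs tail (8661), and days 5 to 10 alone 5944 for head vs tail (9251). Library totals in place of TMM gave 677, 120 and 113 at days 5, 7 and 10, and 17273 for head vs tail, 16153 of them higher. They shift the median of all unigenes by 0.70 for head vs tail, 0.31 for head vs trunk, 0.40 for trunk vs tail and 0.20 at day 1, with 93.5, 77.9, 89.6 and 91.7% of calls higher (49.9, 46.3, 49.9 and 75.0%). Totals without the top unigene shift them by 0.26, 0.37 and -0.11, with 76.8, 81.5 and 35.6% higher. Day 1 gave 57 without the head day 1 library, and day 3 gave 200 with the older edgeR fit. Under library totals 24 of 188 gene results changed sign, 0 relative to the shift of all unigenes; the 9 with a call in either setting turned positive: head vs tail 40S ribosomal protein S3 0.31, METTL3 0.51, the YTHDF unigenes DN5793_c0_g1 0.63, DN6087_c0_g1 0.24, DN77690_c0_g1 0.37 and DN7930_c2_g1 0.58; head vs trunk Ago3 0.0134 and DN77690_c0_g1 0.0270; trunk vs tail DN77690_c0_g1 0.34. Totals without the top unigene gave 0.0758 for Ago3 and 0.0834 for DN77690_c0_g1 in head vs trunk, and Wnt-4 (DN15386_c0_g1) gave 0.35 there at days 5 to 10 alone. Of the 29 day and 35 fragment list tests called, camera with an estimated correlation called 0 and 0, and fry 6 and 52, with 6 and 33 shared. Day 0 counts of 3506, 3103 and 2854 became 720, 735 and 382 at log2 of 2, which is stricter by construction, 1627, 1275 and 1013 with a floor of CPM 5, and 6946 (head vs tail) and 5266 (trunk vs tail) with plain CPM. From day 0 to 10, 1 minus the Spearman correlation changed by -0.0336 between head and tail, -0.0154 between trunk and tail and -0.0128 between head and trunk, where the median difference rose. Alternatives that need normalized values were not run. With 3 counts at 0.107 to 0.252 CPM, lower levels were not detectable at this depth. Of 320 gene results, 315 stayed the same with DESeq2 size factors and 248 with library totals, and of 318 with a DESeq2 test 303 did. Of 65 any-day gene results, 53 stayed the same without trunk, 36 without head and 29 without tail.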

Other observations

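The members of lists named here were chosen only after their values were seen. Some single unigenes of the excretory and immune lists differed between head and tail, although neither list was called. Cubilin (TRINITY_DN5110_c1_g1), a receptor that takes up proteins from filtered fluid in the excretory tubules, averaged 70.3 CPM in head, 54.96 in trunk and 27.5 in tail (log2 1.34 ± 0.09, adjusted p = 2.58e-08, higher on 6 of 6 days). Solute carrier family 12 member 4 (TRINITY_DN22587_c0_g1), a potassium-chloride transporter, averaged 92.7, 177 and 288 CPM (-1.64 ± 0.13, adjusted p = 1.07e-07). The bacterial sensors Peptidoglycan-recognition protein SB1 (TRINITY_DN26383_c0_g1, -0.84 ± 0.17, adjusted p = 0.000765) and 2 (TRINITY_DN7306_c0_g1, -0.80 ± 0.10, adjusted p = 1.18e-05) were lower in head, with -0.13 and -0.10 and no call with library totals, which move all unigenes up by 0.70.

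Over the days, some single unigenes of signalling and tissue remodelling changed. Noggin like protein (TRINITY_DN4735_c2_g1), an inhibitor of BMP signals, rose by 1.01 ± 0.18 at day 1 (any-day adjusted p = 0.00345). The executioner protease caspase-3B (TRINITY_DN6722_c0_g2) fell by 1.01 ± 0.12 at day 5 (any-day adjusted p = 0.00176), from 188 to 83.8 CPM in tail, and the TRAF4-like adaptor (TRINITY_DN5455_c1_g1) by 0.99 ± 0.14. Caspase-3A (TRINITY_DN12631_c0_g1) passed over any day (adjusted p = 0.0154). At day 7 the matrix fibre protein Fibrillin-3 (TRINITY_DN12906_c0_g1) fell by 0.99 ± 0.12 and Matrix metalloproteinase-25 (TRINITY_DN1908_c0_g1), a matrix-cutting enzyme, rose by 0.79 ± 0.18. Each of these any-day calls was lost without tail. In tail, the inhibitory SMAD6/7-2 went from 2.10 to 15.6 CPM between days 0 and 10, SMAD4 from 2.19 to 10.8 and TRAF3 (TRINITY_DN6453_c0_g1) from 3.36 to 30.4, with head minus tail slopes of -0.74 ± 0.10, -0.62 ± 0.11 and -1.16 ± 0.16 (the last at adjusted p = 0.0624 without day 10). Activin 1 (TRINITY_DN78232_c1_g1), a growth signal, went from 18.2 to 2.42 CPM in head and from 41.4 to 46.8 in trunk.

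Lists with no camera call between head and tail included apoptosis (3 of 36 higher, 9 lower, adjusted p = 0.118), collagen and matrix (10 of 41 higher, 12 lower, adjusted p = 0.181), protonephridia (10 of 17 higher, 5 lower, adjusted p = 0.341), oxidative phosphorylation (1 of 23 higher, 3 lower, adjusted p = 0.659) and epidermal lineage (1 of 7 each way, adjusted p = 0.977). Innate immunity had 3 of 7 lower (adjusted p = 0.299). Over any day, collagen and matrix had 13 of 41 called (21 adjusted over the list alone) and intestine 9 of 38 (20 adjusted over the list alone).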
